A study of Mus musculus with 6 samples.

How the data were processed

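Total RNA from 6 mouse cell samples was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels. Groups were taken from the sample titles. The deposited scanner files hold the spot intensity on a linear scale, background-subtracted and detrended within the array by Agilent Feature Extraction 10.7.1.1, per the file headers. The submitters' processing notes name version 9.1 of that program, and which of the versions made the values was not settled. A deposited value table of the whole series held the same intensities, equal at 45018 of 45018 values on each array, with column medians from 181.7 to 269.6. It was therefore on a linear scale and not centred, and using it in place of the scanner files gives the same values. The deposited flags for spots above background, saturated or outlying are yes-or-no marks by the same program, per the file headers.

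Control spots and outlier spots were left out, and repeat spots of a probe were averaged. The main values were log2 of the processed signal minus the array's 75th percentile of it (intensities of 1384 for mES, 1280 for mES + SB431542, 1190 for E3.5 EpiSC, 1801 for E3.5 EpiSC + SB431542, 1228 for E5.5 EpiSC and 1459 for E5.5 EpiSC + SB431542). Each array held 43379 spots for genes, 0 of them saturated, and the median coefficient of variation of repeat spots ran from 5.1% to 7.3%. Of 41174 probes, 24375 were named by matching their transcript accession, without version, to the RefSeq gene table of assembly GRCm38.p6, and the other 16799 were not named here. The file headers name another assembly, so no coordinates are given. The named probes covered 17015 genes, each represented by its probe with the highest mean signal. Of these, 16152 were well above background on at least 1 array and were tested, and 14478 were so on all 6. Among called genes with several probes, 2 of 68 in the comparison of the cell classes and 4 of 111 in that of SB431542 in EpiSCs had a probe with the opposite sign.

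Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. No group has a second array. The comparisons of EpiSCs with mES cells and of treated with untreated EpiSCs therefore took the 2 EpiSC lines as replicates of the class, in a fit of 4 arms over all 6 arrays with 2 residual degrees of freedom. The lone mES arrays were assumed to vary like the EpiSC lines. Nothing says that arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The comparison across lines and that between EpiSC lines used a model of line plus treatment. The lines pair the treated with the untreated arrays, so the count with the line as a block is given beside the count it changes. For SB431542 in EpiSCs and for its difference from mES cells, calls of single genes and lists are given without the block. Single pairs of arrays were described without a test, by a 2-fold rule on genes well above background on the brighter array.

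The slide was read from the files. Slide 1 held both mES and both E5.5 EpiSC arrays, and slides 2 and 3 held 1 E3.5 EpiSC array each. Where a gene was well above background on no array of the dimmer group, its change is given as "at least N-fold": the brighter group's mean against, per array of the dimmer group, the higher of the gene's own signal and the lowest signal among probes well above background. On an array where the gene's own signal is the higher, N rests on that signal as measured, as for Cer1 on the E5.5 EpiSC + SB431542 array. Where only some arrays of the dimmer group were above background, the fitted value is given and holds a signal at background as measured. Examples are Dppa3 and Stra8 on the E5.5 EpiSC array, and Gsc and Mixl1 on the E3.5 EpiSC + SB431542 array.

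Genes were named by rules fixed before the data were examined: the 10 rises and 10 falls with the largest fitted values that passed in a tested comparison, moved the same way in every pair of arrays and were above background on the brighter arm; the 5 with the largest log2 ratios in each direction per pair of arrays; 47 fixed markers, of which 45 were measured (Fgf4 and Nodal had no named probe); and up to 4 members of each list with a camera call. Fitted values that rest on a signal at background have no order, so genes given as "at least N-fold" hold no rank among those named. Not every list member under the last part is printed, and 1 gene that these rules name is not reported here. The 26 gene lists, fixed at the same time, held 502 genes, of which 469 were measured: naive pluripotency, core pluripotency, primed epiblast, mesendoderm and primitive streak, Nodal and Activin feedback and targets, BMP targets, neuroectoderm, neural crest and surface ectoderm, trophectoderm, primitive and visceral endoderm, fibroblast markers, germline, two-cell-like, FGF and ERK response, Wnt targets, LIF and STAT3 response, epithelial, mesenchymal transition, DNA methylation machinery, cell cycle, p53 targets, glycolysis, cholesterol synthesis, imprinted, sex-linked, and heart, blood and neuron markers. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation. The preset test counts genes, whereas the second also rests on the 2 residual degrees of freedom. The estimate was not always above the preset, with 0.00854 for naive pluripotency genes in EpiSCs against mES cells. A call lost in the second test is therefore no sign by itself of correlation between genes. For single pairs a list's median was placed among 10000 random lists of the same size matched on mean signal.

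The fits were tested on simulated data of 16152 genes with 50 changed genes per size. For EpiSCs against mES cells, 0%, 0%, 58% and 90% were recovered at log2 changes of 1, 2, 4 and 6, with 6 false calls, and for SB431542 in EpiSCs 0%, 2%, 74% and 94%, with 1 false call. The simulated noise was independent between arrays, without a difference between lines or a background floor. These rates therefore hold for such data and do not give the error rate of the real fits. Alternatives covered the background correction (normexp with an offset of 50 on the median spot and background signals, as no mean signal column was present), quantile and median scaling, filters on dim genes, the mean over probes, an intensity trend, blocks for line and slide, and leaving out each array. Figures were drawn with matplotlib 3.10.9.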

Results

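Gene expression was measured with one-colour Agilent microarrays in 3 kinds of mouse pluripotent cell, each grown with and without SB431542. Mouse embryonic stem (mES) cells are the naive pluripotent cells of the blastocyst, and epiblast stem cells (EpiSCs) are primed pluripotent cells that resemble the later epiblast and depend on Activin and Nodal signals. The EpiSC lines came from E3.5 embryos, before implantation, and from E5.5 embryos. SB431542 blocks the kinase of the type I receptors for Activin, Nodal and TGF-beta, and treated cells received 20 µM of it daily for 4 days. Each of the 6 groups holds 1 array, so no group has replicates of its own. Between 82.6% and 85.7% of spots on an array were well above background, and 16152 named genes were tested. Signals are given as log2 values relative to the 75th percentile of the array, and the number of arrays limits the precision of every estimate.

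The untreated EpiSCs were set against untreated mES cells to ask how the cell classes differ, with the E3.5 and E5.5 lines as the 2 replicates of the EpiSC class. Fgf5, a growth factor gene of the epiblast after implantation, rose by 6.32 ± 0.60 on the log2 scale (SE, n = 2 EpiSC arrays and 1 mES array, adjusted p = 0.0284). Fgf8 (4.59) and T (3.68), genes of the epiblast and primitive streak, rose too. Genes of naive pluripotency and of the germ line fell, among them Dppa3 (-9.13 ± 1.04, adjusted p = 0.0398), Dppa5a (-9.24), Stra8 (-9.57 ± 0.46, adjusted p = 0.0122) and Dppa4 (-8.51). The core pluripotency factors differed by less than the test could separate, with Pou5f1 at 0.22 ± 0.51 (adjusted p = 0.906), Nanog at -0.28 ± 0.68 (adjusted p = 0.909) and Sox2 at -0.89 ± 0.34 (adjusted p = 0.311).

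Of 19 measured germline genes, 11 fell, 0 rose and 8 did not pass the test (15 fell when adjusted over the list alone). They included Stra8, which marks entry into meiosis, Rhox5 (-7.94), the piRNA pathway gene Mael (-7.35), and the RNA helicase gene Ddx4, which was at least 99.0-fold lower. All 19 had a negative estimate, with a median of -5.39 (adjusted p = 5.12e-17 by camera, adjusted p = 0.269 with an estimated correlation). Of 26 naive pluripotency genes, 7 fell, 0 rose and 19 did not pass (19 fell when adjusted over the list alone), with a median of -3.63 (adjusted p = 2.93e-16, adjusted p = 0.269 with an estimated correlation). Dppa5a, Dppa3, Tdh (-7.41) and Fbxo15 (-5.87) were the largest of these falls. Several naive factors had large estimates that missed the threshold: Zfp42 (-9.35 ± 1.35, adjusted p = 0.0585), Nr0b1 (-8.07), Esrrb (-7.17), Tbx3 (-5.05), Tfcp2l1 (-3.71), Klf4 (-3.55) and Pecam1 (-3.37). Klf2 stood at 0.10, but at -0.01 with normexp and at -1.79 as a mean over its probes. Of 12 genes of the two-cell-like state, 3 fell, namely Zscan4c (-5.68), Usp17la (-4.26) and Tcstv1 (-4.07), and 9 did not pass (6 fell when adjusted over the list alone; median -2.44, adjusted p = 1.4e-05, adjusted p = 0.269 with an estimated correlation).

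Of 25 primed epiblast genes, Fgf5 and Fgf8 rose and 23 did not pass (10 rose when adjusted over the list alone; median 1.22, adjusted p = 5.69e-07, adjusted p = 0.269 with an estimated correlation). Otx2 (1.22), Pou3f1 (0.58) and Dnmt3b (-0.06) were among those that did not. Of 25 mesendoderm and primitive streak genes, T alone rose and 24 did not pass (3 rose when adjusted over the list alone; median 1.34, adjusted p = 0.000845, adjusted p = 0.594 with an estimated correlation). Cer1 (7.71 ± 1.46, adjusted p = 0.0968), Foxa2 (5.95), Gsc (4.51), Eomes (2.71), Mixl1 (1.43) and Sox17 (0.24) had estimates that did not pass. Of 17 Nodal and Activin feedback and target genes, Fgf8 rose and 16 did not pass (2 rose when adjusted over the list alone; median 1.12, adjusted p = 0.00146, adjusted p = 0.594 with an estimated correlation), with Lefty1 at 2.15, Lefty2 at 1.45, Smad7 at 0.38 and Tdgf1 at -0.93. Among 16 Wnt target genes T rose (8 rose and 1 fell when adjusted over the list alone; median 1.72, adjusted p = 0.00103, adjusted p = 0.269 with an estimated correlation). Tgfb2 (3.82) and Zeb2 (3.06) rose among 21 mesenchymal transition genes (3 rose and 1 fell when adjusted over the list alone; median 1.34, adjusted p = 6.78e-06, adjusted p = 0.269 with an estimated correlation), where Cdh2 stood at 3.83 and Vim at 1.27.

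Fibroblast markers would also mark feeder cells. All 25 had a positive estimate (median 1.02, adjusted p = 2.11e-05, adjusted p = 0.594 with an estimated correlation), 0 passed the limma test singly or when adjusted over the list alone, and Tagln (4.20), Timp3 (2.32) and Col1a1 (1.34) were among them. The lines parted here, with medians of 0.12 in the E3.5 line (above 7705 of 10000 random lists) and 2.04 in the E5.5 line (above all of them). Of 36 neuroectoderm genes Zfp521 (3.95) rose and 35 did not pass (6 rose when adjusted over the list alone; median 0.85, adjusted p = 0.000251, adjusted p = 0.459 with an estimated correlation), with Zic1 at 2.82, Hes5 at -0.27, Pax6 at -0.64 and Sox1 at -0.14. Of 18 core pluripotency genes Dppa4 and Dnmt3l (-6.99) fell (3 fell when adjusted over the list alone; median -0.50, adjusted p = 0.0175, adjusted p = 0.594 with an estimated correlation). No single gene passed in the imprinted (16 genes, median 1.21, 6 rose when adjusted over the list alone), LIF and STAT3 response (18 genes, median -0.82, 2 fell when adjusted over the list alone), p53 target (20 genes, median -0.56, 0 when adjusted over the list alone) or cholesterol synthesis lists (19 genes, median 0.45, 0 when adjusted over the list alone). Their camera calls (adjusted p = 9.24e-05, 0.0351, 0.0319 and 0.034) were lost too (adjusted p = 0.269, 0.684, 0.672 and 0.605 with an estimated correlation).

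The lists without a camera call held few changed genes. Sox9 (4.23) rose among 23 neural crest and surface ectoderm genes (median 0.25, adjusted p = 0.0597). Rhox9 (-4.14), an X-linked homeobox gene, fell among 19 trophectoderm genes (median -0.14, adjusted p = 0.59), in which Cdx2 stood at 2.74, Krt8 at 3.90 and Krt18 at 3.09. Apoa2 (-5.78) and Cubn (-3.31) fell among 26 primitive and visceral endoderm genes (median 0.22, adjusted p = 0.64), in which Gata4 stood at -0.67 and Gata6 at -0.03. Dnmt3l fell among 12 genes of the DNA methylation machinery (median -0.18, adjusted p = 0.382), and the cyclin gene Ccnd2 (4.11) rose among 29 cell cycle genes (median -0.14, adjusted p = 0.725). No gene passed among the BMP target (median 0.49, adjusted p = 0.0522, Id1 at 0.85 and Id3 at 0.72), FGF and ERK response (median 0.04, adjusted p = 0.499), epithelial (median -1.29, adjusted p = 0.222, Cdh1 at -1.40), glycolysis (median -0.04, adjusted p = 0.725), sex-linked (median -2.0, adjusted p = 0.524) or heart, blood and neuron lists (median -0.09, adjusted p = 0.874). When adjusted over the list alone, 3 neural crest genes rose and 1 fell, 2 trophectoderm genes rose and 5 fell, and 1 endoderm gene rose and 3 fell. By the same measure, 2 DNA methylation genes fell, and 1 cell cycle and 1 epithelial gene rose. The other lists named with them had 0. The cell cycle list and the heart, blood and neuron list had a negative median and a positive mean.

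By limma with Benjamini-Hochberg adjustment, 63 genes were higher and 179 lower in EpiSCs, of 2642 at an unadjusted p under 0.05, and all 242 moved the same way in both lines. That agreement is no separate support, because the difference between the lines is the error of the test. The 10 rises named by their fitted values were Fgf5, Chst1 (5.56), Slc39a8 (5.33), Cd59a (5.16), Heph (5.02), Dhrs3 (4.86) and Meis2 (4.66), and, without a rank, Rgs8 (at least 33.9-fold), Il7 (at least 12.3-fold) and Klhl4 (at least 6.19-fold). The 10 falls so named were Stra8, Dppa5a, Dppa3, Cyct (-8.96) and Dppa4, and, without a rank, Fmr1nb (at least 698-fold), Pramel13 (at least 565-fold), Morc1 (at least 518-fold), Rbmxl2 (at least 445-fold) and Sycp1 (at least 110-fold). Normexp background correction gave 69 higher and 113 lower, and genes above background on all 6 arrays gave 124 higher and 148 lower. The count was 0 without the E3.5 EpiSC + SB431542 array and 0 without the E5.5 EpiSC + SB431542 array, each with 3279 genes at an unadjusted p under 0.05.

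The effect of SB431542 in EpiSCs was tested with 2 treated against 2 untreated arrays. The line was not a block in this fit, so a steady gap in level between the lines counts as error in the calls and list tallies below. With the block 810 genes passed in place of 338, so a gene said not to pass may pass there. Pou5f1, the gene for the pluripotency factor Oct4, fell by 10.69 ± 0.42 on the log2 scale (SE, n = 2 and 2, limma adjusted p = 0.0228), and Nanog fell by 7.68 ± 0.55 (adjusted p = 0.0233). Lefty1, a feedback inhibitor of Nodal, fell by 10.36 ± 0.58 and Fgf5 fell by 9.86 ± 0.49. Genes of the early nervous system rose, among them the Notch effector Hes5 (6.97 ± 0.47, adjusted p = 0.0228), Nr2f1 (6.19) and Zic1 (5.78). Sox2, which pluripotent and neural progenitor cells share, stood at 0.49 ± 0.28 and did not pass (adjusted p = 0.383).

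Of 36 neuroectoderm genes, 9 rose, 0 fell and 27 did not pass (22 rose and 2 fell when adjusted over the list alone). Hes5, Nr2f1, Zic1 and Nr2f2 (5.57) led them, and the median was 1.98 (adjusted p = 9.79e-17, adjusted p = 0.38 with an estimated correlation). Pax6 stood at 3.11 (adjusted p = 0.0525) and Sox1 at 0.56. Of 17 Nodal and Activin feedback and target genes, 6 fell, 0 rose and 11 did not pass (11 fell when adjusted over the list alone; median -2.23, adjusted p = 1.93e-07, adjusted p = 0.38 with an estimated correlation). Besides Lefty1, these were Cer1 (at least 449-fold lower), Tdgf1 (-6.82), Lefty2 (-6.09), Fgf8 (-5.83) and Eomes (-4.92), while Smad7 (-1.96) and Gsc (-7.06) did not pass. Of 18 core pluripotency genes, 6 fell and 12 did not pass (11 fell when adjusted over the list alone; median -1.85, adjusted p = 1.24e-07, adjusted p = 0.38 with an estimated correlation), with Utf1 at -5.74. Of 26 naive pluripotency genes, Nanog, Fbxo15 (-3.92) and Nr5a2 (-2.05) fell (6 fell and 1 rose when adjusted over the list alone; median -1.04, adjusted p = 0.0147, adjusted p = 0.38 with an estimated correlation). Zfp42 (-1.62), Klf4 (-0.14), Klf2 (-0.22), Esrrb (-0.72), Tbx3 (0.84), Tfcp2l1 (-2.48), Nr0b1 (-0.39) and Pecam1 (-0.83) did not pass, and Dppa3 was at least 1.52-fold lower, also without passing.

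Of 25 primed epiblast genes, 5 fell and 1 rose (11 fell and 3 rose when adjusted over the list alone; median -1.60, adjusted p = 0.00845, adjusted p = 0.38 with an estimated correlation). Fgf5, Pim2 (-6.05), Fgf8 and the DNA methyltransferase gene Dnmt3b (-4.18) led the falls, Sfrp2 (3.32) rose, and Otx2 (-4.05) and Pou3f1 (-2.04) did not pass. Of 25 mesendoderm and primitive streak genes, Cer1, Lefty2, T (-4.95) and Eomes fell and 21 did not pass (7 fell and 1 rose when adjusted over the list alone; median -0.81, adjusted p = 0.00759, adjusted p = 0.551 with an estimated correlation), with Foxa2 at -1.74, Mixl1 at -2.15 and Sox17 at -0.52. Of 20 epithelial genes, Epcam (-5.51) and Marveld2 (-2.80) fell and 18 did not pass (14 fell when adjusted over the list alone). All 20 had a negative estimate (median -2.57, adjusted p = 1.21e-07, adjusted p = 0.38 with an estimated correlation), with the E-cadherin gene Cdh1 at -5.68 ± 0.91 (adjusted p = 0.0636). The N-cadherin gene Cdh2 stood at 2.13 and Vim at 0.98, and of 21 mesenchymal transition genes 0 passed by limma (median -0.02, adjusted p = 0.204). Fibroblast markers had a median of -0.16 (adjusted p = 0.898), with Col1a1 at 0.12. The lines differed here, without a test. In the E3.5 pair the fibroblast median was 0.53, above 9999 of 10000 random lists, with 10 markers at least 2-fold higher and 4 lower. In the E5.5 pair it was -0.73, below all 10000, with 2 higher and 9 lower.

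Among FGF and ERK response genes, Etv1 (-3.53), Etv4 (-3.08) and Spry4 (-2.77) fell of 18 (7 fell and 1 rose when adjusted over the list alone; median -0.94, adjusted p = 0.00056, adjusted p = 0.38 with an estimated correlation). Pax3 (5.33) rose among 23 neural crest and surface ectoderm genes (5 rose when adjusted over the list alone; median 0.53, adjusted p = 0.0147, adjusted p = 0.38 with an estimated correlation). The imprinted genes Phlda2 (-3.93) and Ndn (1.91) went opposite ways (6 rose and 2 fell when adjusted over the list alone; median 0.29, adjusted p = 0.0208, adjusted p = 0.38 with an estimated correlation). Of 21 glycolysis genes 0 passed singly, yet 16 fell when adjusted over the list alone, with the glucose transporter genes Slc2a3 at -2.71 and Slc2a1 at -1.99 (median -1.16, adjusted p = 3.86e-06, adjusted p = 0.38 with an estimated correlation). Single genes likewise did not pass in the cholesterol synthesis list (2 fell when adjusted over the list alone; median -0.83, adjusted p = 6.32e-05, adjusted p = 0.38 with an estimated correlation), the p53 target list (5 fell when adjusted over the list alone; median -0.78, adjusted p = 0.00342, adjusted p = 0.538 with an estimated correlation) or the BMP target list (6 rose and 2 fell when adjusted over the list alone; median 1.11, adjusted p = 0.00489, adjusted p = 0.38 with an estimated correlation). Id1 stood at 2.33 and Id3 at 1.70 in the last of these.

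In the other lists, T and Dkk1 (-3.43) fell among Wnt targets (median -0.71, adjusted p = 0.215), and Bmp8b (-3.06) fell among trophectoderm genes (median -0.72, adjusted p = 0.148), where Cdx2 was at least 28.7-fold lower without passing (adjusted p = 0.173). That bound is for the mean over the lines. Untreated Cdx2 was far dimmer in the E5.5 than in the E3.5 line, so the bound need not hold in the E5.5 line. Krt8 stood at -2.28 and Krt18 at -1.60. The basement membrane gene Lama1 (3.47) and Plat (2.18) rose among primitive and visceral endoderm genes (median -0.04, adjusted p = 0.316), with Gata4 at 0.35 and Gata6 at -0.35. Tex19.1 (-4.59) fell among germline genes (median -0.66, adjusted p = 0.135), and Dnmt3b was the fall in the DNA methylation list (median -0.01, adjusted p = 0.848). The two-cell-like (median -0.60, adjusted p = 0.0624), LIF and STAT3 (median -0.30, adjusted p = 0.407), cell cycle (median -0.32, adjusted p = 0.283), sex-linked (median -0.73, adjusted p = 0.848) and heart, blood and neuron lists (median -0.06, adjusted p = 0.135) held no changed gene. When adjusted over the list alone, 2 Wnt targets rose and 7 fell, 1 trophectoderm gene fell, and 2 endoderm genes rose and 1 fell. By the same measure, 2 germline genes rose and 3 fell, 1 DNA methylation gene rose and 2 fell, and 1 mesenchymal transition gene rose and 1 fell. The fibroblast list and the lists without a changed gene had 0. The primitive and visceral endoderm, mesenchymal transition, fibroblast, DNA methylation and heart, blood and neuron lists had a negative median where camera gave the upward direction.

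By limma 144 genes rose and 194 fell with SB431542 in EpiSCs, of 3201 at an unadjusted p under 0.05, and all 338 moved the same way in both lines. Here too a difference between the lines counts as error, so the agreement is largely built into the call. Besides the genes above, the 10 rises named by their fitted values held Bhlhe23 (6.28), Msx3 (5.85), Mlc1 (5.68), Ednrb (5.64), Nhlh1 (5.56) and Tenm2 (5.46). The 10 falls so named also held Ucma (at least 153-fold), Eras (-6.71), Mmp25 (at least 67.7-fold) and Car2 (-6.28). With the line as a block, 346 genes rose and 464 fell, and these 810 held all 338. The count was 0 without the E3.5 EpiSC + SB431542 array (2418 at an unadjusted p under 0.05) and 0 without the E5.5 EpiSC + SB431542 array (5030), and 195 without the E3.5 EpiSC array.

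**Figure D1:**
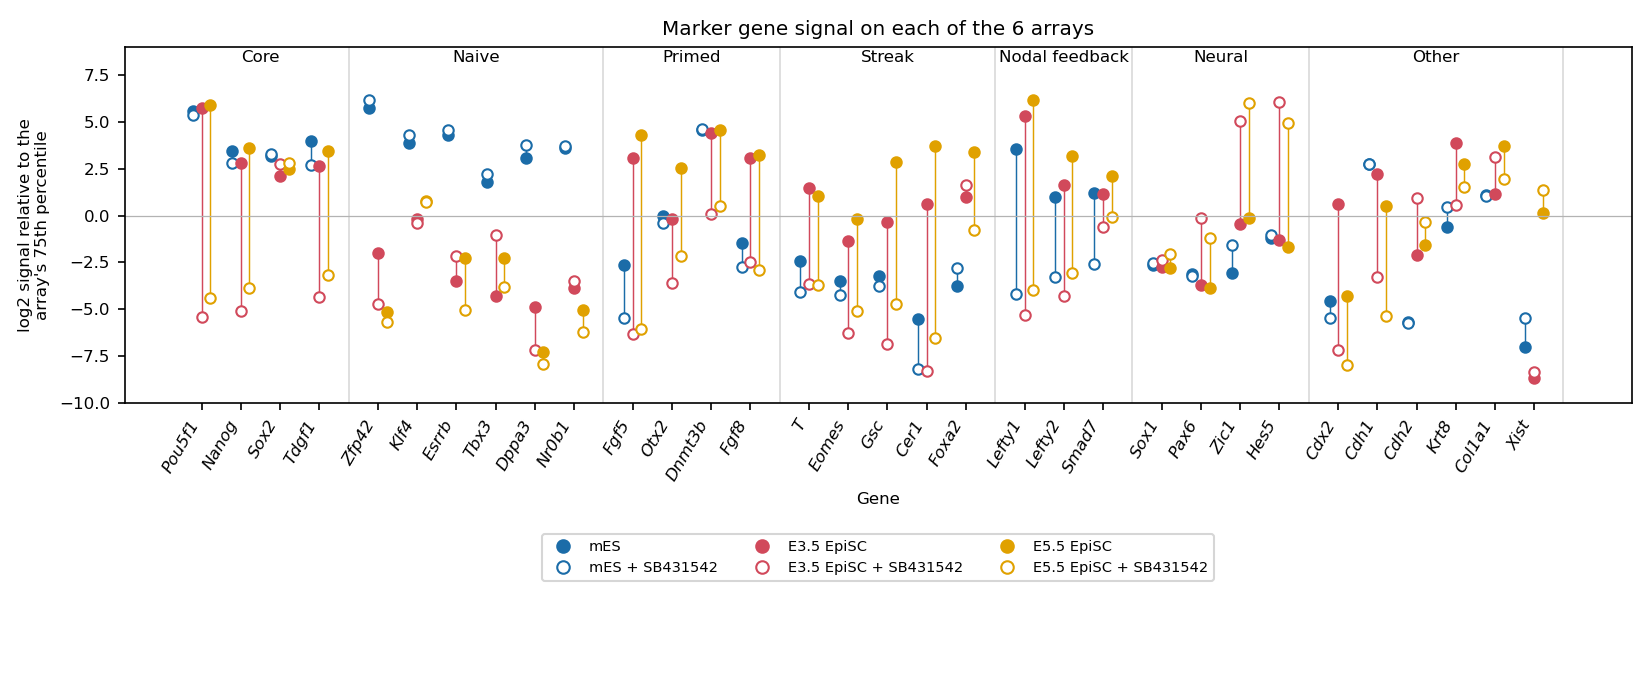
Log2 signal of marker genes relative to the 75th percentile of each array (vertical axis) on the 6 arrays, with filled points for untreated and open points for treated cells, each joined by a line within its cell line. Pou5f1 went from 5.73 to -5.39 in the E3.5 EpiSC line, from 5.88 to -4.38 in the E5.5 EpiSC line and from 5.59 to 5.35 in mES cells; levels are not comparable between genes.

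In mES cells, 1 treated and 1 untreated array were set side by side, with no test. Lefty1 was lower by far in treated cells (log2 signal -4.21 against 3.58), as was Lefty2 (-3.28 against 0.97). Kcnv1 (at least 3.78-fold) and St6galnac1 (at least 3.61-fold) were also among the 5 reductions named by their log2 ratios. The 5 increases so named were Car10 (at least 6.43-fold), Lcn2 (log2 ratio 4.15), Olfr811 (at least 4.23-fold), Defb20 (at least 16.1-fold) and Hsf3 (at least 4.33-fold). Pou5f1 (5.35 against 5.59) and Nanog (2.81 against 3.48) were each less than 2-fold apart. Of 17 Nodal and Activin feedback and target genes, 9 were at least 2-fold lower and 0 higher, and none of 10000 random lists matched on signal had a lower median than theirs (-1.25). Of 26 primitive and visceral endoderm genes, 10 were at least 2-fold higher, and none of the random lists had a higher median (0.53), while the fibroblast median (0.43) was likewise above all of them. In all, 227 genes were at least 2-fold higher and 182 at least 2-fold lower (100 and 81 with normexp).

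Whether the response differed between EpiSCs and mES cells was tested as an interaction, in which the lone mES arrays were assumed to vary like the EpiSC lines. The lists described below were not the only ones with a camera call. The others were naive pluripotency, primed epiblast, Nodal and Activin, BMP target, trophectoderm, FGF and ERK response, p53 target and glycolysis. Their calls were lost with an estimated correlation. Among the largest estimates in the lists were those of Pou5f1 (-10.45), Nanog (-7.02) and Hes5 (6.83), and none passed. By limma 0 genes passed, with 1109 at an unadjusted p under 0.05 and a smallest adjusted p of 0.286. Neuroectoderm genes had a median of 2.14 (13 rose when adjusted over the list alone; adjusted p = 1.27e-18 by camera, adjusted p = 0.516 with an estimated correlation). Core pluripotency genes had a median of -1.80 (7 fell when adjusted over the list alone; adjusted p = 7.38e-08, adjusted p = 0.516 with an estimated correlation), and epithelial genes of -2.57 (2 fell when adjusted over the list alone; adjusted p = 5.41e-07, adjusted p = 0.516 with an estimated correlation).

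Across the 3 lines, treated against untreated with the line as a term, the Nodal and Activin list had a median of -2.58, and 16 of its 17 members had a negative estimate (13 fell when adjusted over the list alone; adjusted p = 9.03e-09 by camera, adjusted p = 0.447 with an estimated correlation). Glycolysis genes had a median of -0.96 (15 fell when adjusted over the list alone; adjusted p = 1.06e-07, adjusted p = 0.447 with an estimated correlation), and all 19 cholesterol synthesis genes a negative estimate (0 when adjusted over the list alone; adjusted p = 1.7e-07, adjusted p = 0.447 with an estimated correlation). The neuroectoderm list had a median of 1.38, with 31 of 36 estimates positive (camera adjusted p = 2.25e-10, adjusted p = 0.447 with an estimated correlation). All 20 epithelial genes had a negative estimate (median -1.72, camera adjusted p = 5.7e-07, adjusted p = 0.447 with an estimated correlation). In the mES pair alone the medians of the neuroectoderm and epithelial lists were -0.01 and -0.13. Other lists also had camera calls, among them core pluripotency, two-cell-like and FGF and ERK response genes. These too were lost with an estimated correlation. Singly, 0 genes passed by limma, with 1397 at an unadjusted p under 0.05 and a smallest adjusted p of 0.502. The count was 810 without the mES array or without its treated partner, and 3 without either E5.5 EpiSC array. With the slide as a fixed block it was 0, with 378 at an unadjusted p under 0.05. That fit rests on the mES and E5.5 EpiSC arrays of slide 1, because each E3.5 EpiSC array lies alone on its slide.

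The responses of the lines share no arrays, so their overlap could be counted. With SB431542 in the E3.5 EpiSC line, 1843 genes were at least 2-fold higher and 3177 lower, and in the E5.5 EpiSC line 1046 were higher and 1413 lower (596 and 2009 with normexp). Of these, 772 were higher in both, against 119 for independent lists, and 968 were lower in both, against 278. Across genes the log2 ratios of the lines correlated at r = 0.697, where genes are not independent replicates. With mES cells the correlation was r = 0.137 for the E3.5 line and r = 0.127 for the E5.5 line. Of the 227 genes higher in mES cells, 73 were higher and 33 lower in the E3.5 line, and 30 were higher and 50 lower in the E5.5 line. Of the 182 genes lower in mES cells, 83 were lower and 31 higher in the E3.5 line, and 78 were lower and 15 higher in the E5.5 line. In all 3 lines 21 genes were higher, against 10.8 if the mES response were independent of what the EpiSC lines share, and 70 were lower, against 10.9. The latter held Lefty1, Lefty2, Fgf5, Smad7 and T, and the former Lama1, Zic1 and Meis1. In the E3.5 line Hes5 (7.36), Nr2f1 (7.18), Nhlh2 (at least 90.4-fold), Nhlh1 (6.69) and Bhlhe23 (6.57) were the 5 increases named by their log2 ratios, and Pou5f1 (-11.13), Trap1a (at least 723-fold), Lefty1 (-10.60), Fgf5 (-9.36) and Ucma (at least 131-fold) the 5 reductions. In the E5.5 line they were Hes5 (6.58), Mlc1 (6.57), Zic1 (6.09), Bhlhe23 (5.98) and Msx3 (5.97), and Fgf5 (-10.36), Pou5f1 (-10.26), Cer1 (at least 1213-fold), Lefty1 (-10.11) and Trh (-8.45). Both E3.5 arrays lay on slides of their own, whereas the E5.5 pair lay within slide 1, so the responses shared by the lines were also present within a slide.

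**Figure D2:**
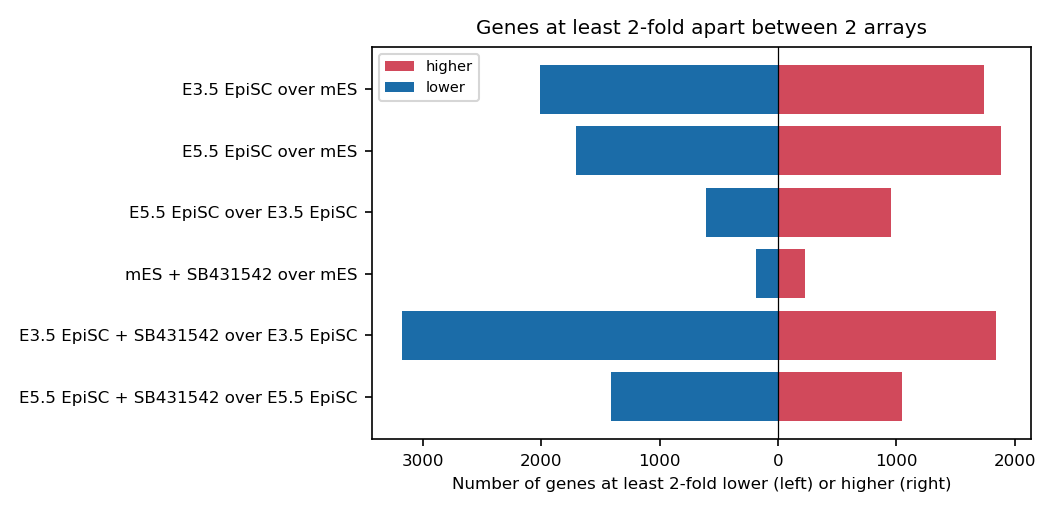
Number of genes at least 2-fold lower (left) or higher (right) in each of 6 pairs of single arrays. The E3.5 EpiSC line had 3177 lower and 1843 higher with SB431542, and the mES cells 182 and 227.

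The EpiSC lines were set against each other over treated and untreated arrays. Xist, the RNA that silences an X chromosome, was at least 169-fold higher in the E5.5 line, and the Y-linked gene Uty at least 15.4-fold lower, and neither passed (limma adjusted p = 0.071 for both). Fibroblast markers had a median of 0.85 (0 when adjusted over the list alone; adjusted p = 0.00391, adjusted p = 0.869 with an estimated correlation), with S100a4 at 2.68 and Ccl2 at 1.99. LIF and STAT3 response genes had a median of 0.77 (1 rose when adjusted over the list alone; adjusted p = 0.00391, adjusted p = 0.869 with an estimated correlation), with Bcl3 at 2.56 and Socs3 at 1.96. Epithelial genes had a median of -1.01 (0 when adjusted over the list alone; adjusted p = 0.0106, adjusted p = 0.869 with an estimated correlation), with Esrp1 at -2.05 and Cdh1 at -1.88. The neuroectoderm list (median -0.40, 0 when adjusted over the list alone, adjusted p = 0.0332) and the sex-linked list (median -5.92, 1 rose and 3 fell of 5 when adjusted over the list alone, adjusted p = 0.0104) had camera calls that were lost too (adjusted p = 0.869 with an estimated correlation for both). By limma 0 genes passed, with 1265 at an unadjusted p under 0.05; the count was 4 without either mES array and 6 without either E5.5 EpiSC array. The E3.5 arrays share no slide with any other, so this comparison alone does not separate slide from line.

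Untreated, 958 genes were at least 2-fold higher and 606 lower in the E5.5 than in the E3.5 EpiSCs (1068 and 164 with normexp). Besides Xist, the chloride channel regulator gene Clca3a1 (at least 10-fold), the chemokine genes Ccl11 (at least 39.0-fold) and Cxcl5 (log2 ratio 5.25), and Agtr2 (4.86) were the 5 increases named by their log2 ratios. Pmaip1 (-6.84) and the Y-linked Ddx3y (-6.64), Eif2s3y (-6.43), Uty and Rbmy (at least 9.32-fold) were the 5 reductions. Of 25 fibroblast markers 14 were at least 2-fold higher and 0 lower. Of 20 epithelial genes 14 were at least 2-fold lower and 0 higher, with a median of -1.72, below all 10000 random lists. Of 17 Nodal and Activin genes 6 were at least 2-fold higher and 0 lower, with a median of 0.84, above all of them. Cdx2, a trophectoderm and posterior gene, had a log2 signal of 0.62 in E3.5 EpiSCs, -4.28 in E5.5 EpiSCs and -4.57 in mES cells.

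Against mES cells, E3.5 EpiSCs had 1742 genes at least 2-fold higher and 2007 lower (1283 and 1197 with normexp, 1539 and 1429 among genes above background on all 6 arrays). The E5.5 EpiSCs had 1889 and 1705 (2041 and 935 with normexp). The 5 increases named by their log2 ratios in the E3.5 line were Cer1 (6.17), Hoxb8 (at least 12.6-fold), Fgf5 (5.69), Chst1 (5.24) and Cdx2 (5.19). The 5 reductions were Fmr1nb (at least 750-fold), Pramel13 (at least 607-fold), Rbmxl2 (at least 478-fold), Ooep (at least 550-fold) and Stra8 (-9.18). In the E5.5 line, on the slide of the mES array, they were Cer1 (9.26), Xist (at least 115-fold), Foxa2 (7.15), Gad2 (at least 93.9-fold) and Fgf5 (6.94), and Fmr1nb (at least 650-fold), Zfp42 (-10.92), Rbmxl2 (at least 414-fold), Pramel13 (at least 526-fold) and Morc1 (at least 490-fold). The fibroblast median was 0.12 in the E3.5 line and 2.04 in the E5.5 line, where 21 of 25 markers were at least 2-fold higher.

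**Figure D3:**
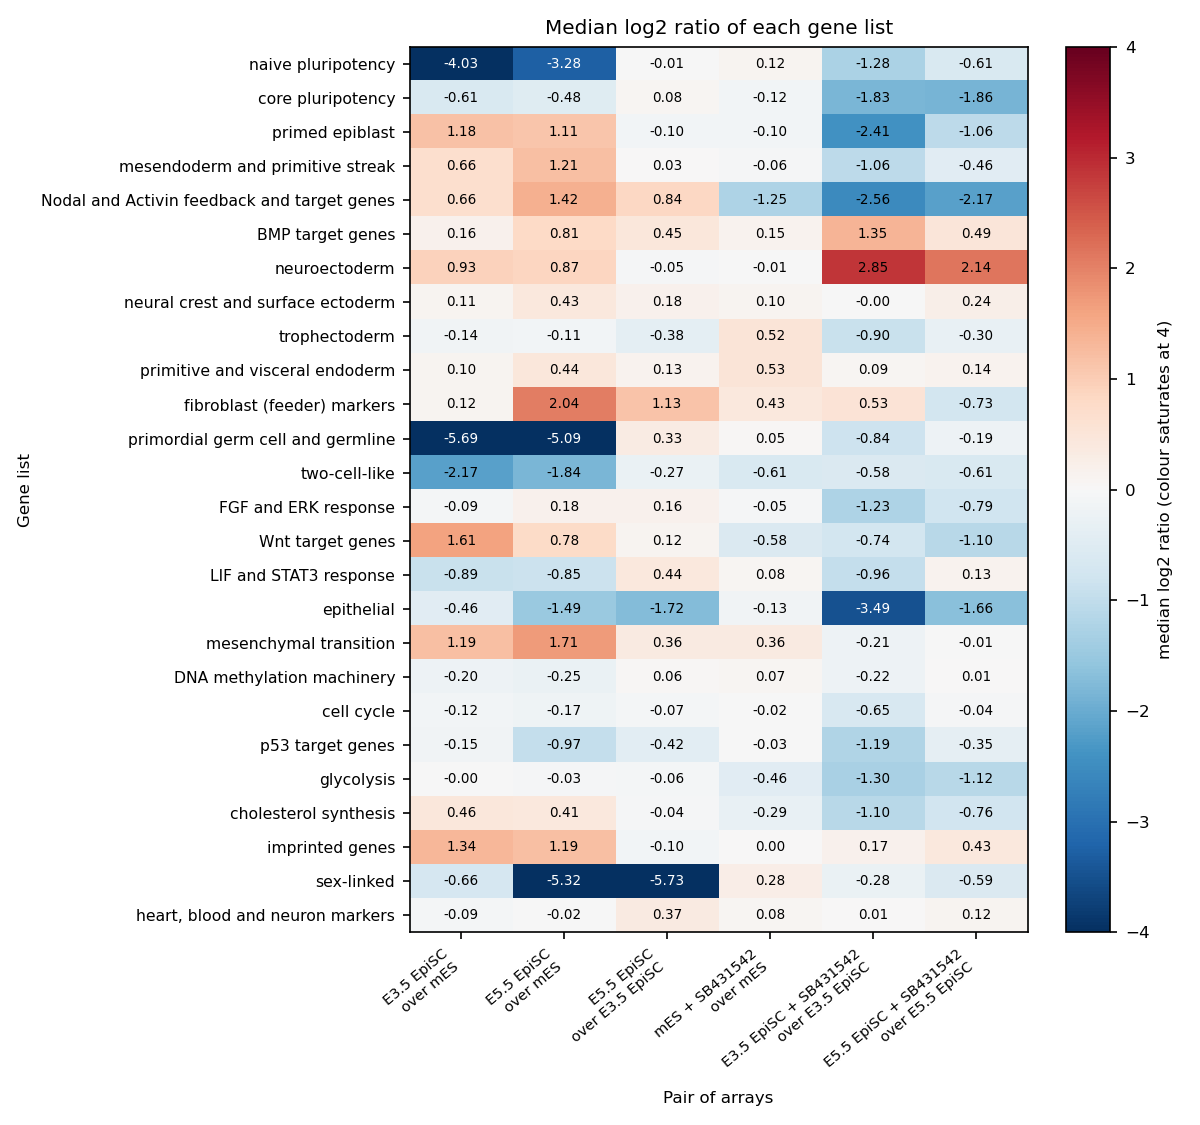
Median log2 ratio of each of 26 gene lists (vertical axis) in each pair of arrays (horizontal axis), coloured and printed in each cell. The germline list had medians of -5.69 and -5.09 in the EpiSC lines over mES cells, and the neuroectoderm list 2.85 and 2.14 with SB431542 in the EpiSC lines.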

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

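The bounds for the tests of array scaling, spike-ins and fibroblast markers in this part were written before their results were seen, and the interval and limit given with 2 of them were added after. The genes below moved with SB431542 in opposite directions between cell lines, each with 1 pair of arrays per line, and the differences between the EpiSC lines were not tested.

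In the EpiSC lines, the naive pluripotency gene Esrrb had a log2 ratio of 1.35 in the E3.5 line and -2.79 in the E5.5 line, and Tbx3 had 3.25 and -1.57. The collagen gene Col1a1 had 2.0 in the E3.5 line and -1.75 in the E5.5 line. The glutamate decarboxylase gene Gad2 had 1.09 and -2.31, and the angiotensin receptor gene Agtr2 3.05 and -2.07. The keratin gene Krt8 had 1.04 in mES cells and -2.28 in EpiSCs (-3.29 in the E3.5 line and -1.27 in the E5.5 line), an interaction of -3.32 ± 0.92 that did not pass by limma (adjusted p = 0.531).

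More genes were at least 2-fold apart with SB431542 in the E3.5 line (5020) than in the E5.5 line (2459). A distorted hybridization across slides is argued against by the spike-in probes, whose log2 ratio within the E3.5 pair had an SD of 0.223 over 9 probes (upper 95% limit 0.427), below the bound of 0.5. The same SD was 0.442 for E5.5 EpiSC over mES within slide 1 and 0.1 for E5.5 over E3.5 EpiSC across slides. It thus did not follow the slides, which limits this argument. For E3.5 EpiSC over mES it was 0.528. For mES + SB431542 over mES the SD was 0.277. The upper limits of the pairs with the untreated mES array were 0.847 (E5.5), 1.01 (E3.5) and 0.531 (treated mES), all past 0.5. This bears on the comparison of EpiSCs with mES cells, on SB431542 in mES cells and on the interaction. A change in feeder cells stays open. The fibroblast median was 0.532 in the treated and untreated E3.5 pair (95.7% interval -0.47 to 1.27, which reaches past the bound of 1) and above 9999 of 10000 random lists. In the E5.5 pair it was -0.731 and below all 10000, so the medians lay 1.26 apart. Array scaling or background correction stays open as an explanation, and its test met the bound written beforehand in favour of it. The ratio of the counts was 2.04 with the main values, 1.93 with quantile scaling and 2.05 with median centring but 1.36 with normexp. The low ratio thus came with the background correction and not with the other scalings. Among genes above background on all 6 arrays the counts were 4117 (E3.5) and 2053 (E5.5), so leaving out dim genes did not close the gap. Whether low signals account for the ratio with normexp was not tested. A difference between the lines is also open and untested, and the E3.5 pair spans slides that hold no other array.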

How the results depend on the processing

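The alternatives with probes that have no gene name were chosen after seeing the data; the others were planned. For EpiSCs against mES cells, counts stayed within 1.5 times of 242 except with an intensity trend (675), with treated and untreated arrays averaged (1704) and with unnamed probes included (376), and ran from 0 to 242 when 1 array was left out. For SB431542 in EpiSCs (338), the count was 540 with genes above background on all 6 arrays, 963 with a trend and 810 with the line as a replicate block, and ran from 0 to 338 without 1 array. The interaction gave 2 with a trend and otherwise 0, the block included, and from 0 to 0 without 1 array. The treatment across lines gave 0 in every alternative with all arrays, no replicate block included, and 0 to 810 without 1 array. The comparison of the EpiSC lines gave 4 with the EpiSC arrays alone and 0 to 6 without 1 array. Some of these values follow from the design. An array alone in its arm carries no error, so the counts of 242 and 338 could not change when such an mES array was left out. Without an mES array, the treatment across lines is the EpiSC fit with the line as a block (810). The comparison of the lines is then that of the EpiSC arrays alone (4). The cause of the other moves was not tested. A similar count also did not mean the same genes. For EpiSCs against mES cells, only part of the 242 genes passed with normexp or among genes above background on all 6 arrays. The random slide block was not run because its correlation could not be estimated, and the fixed slide block could be fitted only across lines. Apart from the count for SB431542 in EpiSCs, the blocks changed no count of a tested comparison. Single pairs gave 2480 with normexp (E3.5 EpiSC over mES) and 181 (mES treatment), and a 4-fold rule gave 1311, 1290, 371, 83, 1618 and 879 in the order E3.5 over mES, E5.5 over mES, E5.5 over E3.5, then treatment in mES, E3.5 and E5.5. Of the named genes' alternatives 1503 were the same, 111 lost and 61 gained a call and 33 turned sign, none of them a called gene. Of the lists' alternatives 61 were the same and 65 lost the call. Every list call was lost with an estimated correlation. With quantile scaling, only the calls of glycolysis in the interaction and of neuroectoderm between the EpiSC lines were lost. Array medians differed by at most 0.13 under normexp. Signal over background limits the dim genes, given as bounds.

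The turned signs for EpiSCs against mES cells were, with normexp, Klf2 -0.01 and Gata6 0.08; with quantile scaling, Dnmt3b 0.05; with the mean over probes, Klf2 -1.79 and Gata6 0.60; and averaged over treatment, where treated arrays enter, Pou5f1 -5.01, Klf2 -0.07, Otx2 -0.63, Sox17 -0.25, Sox1 0.08, Pax6 0.97 and Hes5 3.14. Over the arrays left out in turn, Nanog ran from -0.68 (without E5.5 EpiSC) to 0.12 (without E3.5 EpiSC), Dnmt3b from -0.14 to 0.02, Otx2 from -0.14 to 2.58, Sox17 from -0.15 to 0.64, Smad7 from -0.10 to 0.86, Gata6 from -0.11 to 0.05 and Xist from -1.64 to 7.18. For SB431542 in EpiSCs, Gata4 was -0.20 with normexp and -0.09 with the mean over probes. Over the arrays left out in turn, Tbx3 ran from -0.56 to 2.23, Nr0b1 from -1.75 to 0.96, Gata4 from -0.05 to 0.74, Col1a1 from -1.16 to 1.41, Klf4 from -0.69 to 0.42, Esrrb from -2.17 to 0.74 and Xist from -4.07 to 5.63. The cause was not tested.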

Other observations

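The slide test of the testis-expressed genes, both tests of Xist and the Y-linked genes, and the interval and the comparison with the smallest fall given below for the testis genes were chosen after the result was seen.

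With SB431542 in mES cells, 6 of 12 two-cell-like genes were at least 2-fold lower and 0 higher (median -0.61, below all 10000 random lists), and 4 of 16 Wnt target genes were lower (median -0.58, also below all). None of the 21 glycolysis genes was at least 2-fold higher and 1 was lower (median -0.46, below all). Trophectoderm genes had a median of 0.52 and mesenchymal transition genes of 0.36, both above all random lists, in 1 pair of arrays without a test.

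The 10 falls named for EpiSCs against mES cells held genes known from testis, such as Fmr1nb, Rbmxl2, Stra8 and Sycp1. A slide difference is argued against by the treated E5.5 and mES arrays, which share slide 1 and did not enter the fitted differences that ranked the 10 genes. The treated E5.5 array did enter the error of the test that the genes had to pass, so the choice was not fully independent of it. The median difference between these treated arrays was -9.66 with signals at background raised to the lowest one above it, and each of the 10 was at -7.0 or below. The germline list, fixed beforehand, had a median of -5.09 in the untreated arrays of the same slide, with 16 of 19 genes at least 2-fold lower. RNA of adult testis in the mES sample, as the cause of all these falls, was examined with the fixed testis genes. Of 16 fixed testis genes 14 had a probe, and their median difference was -0.293 (98.7% interval -1.52 to 0.44). The interval reaches below -1, the bound written beforehand to exclude testis RNA, and lies above -3, the bound written for it. The smallest of the 10 falls was -6.78, and the median lies short of it by more than 2 times the SD of the testis genes (1.87). Their median level in mES cells was only -4.09, against 3.05 for the 10 genes. Most testis genes were thus too dim to fall that far, so the comparison with the smallest fall decides nothing. The abundant sperm transcripts differed little, with Prm1 at -0.04, Prm2 at 0.44 and Akap4 at -0.15. Of the 14 genes, 4 were lower in EpiSCs by over 1. Ldhc (-6.58) was so in both lines, Smcp (-2.29) and Odf1 (-1.52) mainly on the E3.5 array, and the other, Pgk2, was not above background in mES cells. RNA of adult testis is therefore not excluded, and RNA of earlier germ cells, which lack sperm transcripts, stays open. Another hypothesis is that the mES cells themselves expressed these germline genes, which was not tested further.

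Xist was well above background in both E5.5 EpiSC arrays (0.15 and 1.38) and in neither E3.5 array, while the mean of 4 Y-linked genes was -5.89 and -6.90 in the E5.5 line against -1.04 and -2.28 in the E3.5 line and -0.89 in untreated mES cells. Xist was also above background in treated mES cells (-5.49). Of the 4 Y-linked genes, 3 were above background on the untreated and 2 on the treated E5.5 array. Ddx3y, Eif2s3y and Uty were lower in the E5.5 than in the E3.5 line in both states. Kdm5d stood at -5.21 against -4.63 untreated and at -5.81 against -8.15 treated. An exchange of 1 E5.5 array with an array of another line is argued against by these signals. Treated and untreated arrays of a line differed by at most 1.54 in Xist or in the mean of the Y-linked genes. A swap of treated and untreated arrays of a line, or of mES and E3.5 arrays, would hardly change these signals, so it was not tested. A slide difference is argued against because on slide 1 alone the means of the 2 E5.5 and the 2 mES arrays differed by 5.59 in the Y-linked genes, the smaller of the 2 differences. A candidate explanation is that the E5.5 line is female and the others male, as a hypothesis from the same data. The Xist signal in treated mES cells and the Y-linked signals above background in the E5.5 line do not go with it. The labels used here give no sex.

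For SB431542 across the 3 lines, 10 splits of the 6 arrays are too few to give a share under 0.05. The real split gave 0 genes and the highest of the others 0, so all 10 were as large. With a real count of 0 any split is as large, so the comparison decides nothing.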
